A study of Mus musculus with 24 samples.

How the data were processed

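RNA of NK cells, CD8a+ DC and CD11b+ DC sorted from the spleens of mixed bone marrow chimeras was measured on 24 one-colour Affymetrix arrays, 1 per sample. Per the labels' protocols, RNA went through successive rounds of amplification before labelling, and the arrays were hybridised in 3 batches of chips. The deposited values are log2 probe set values that the authors normalized together. RMA and limma are named for this per the submitters' processing notes, with versions not given in the sources used here, and it is not stated whether a batch mean was removed. Removing each letter's mean cannot change a fit with the letter term, but fits without it would then count too many degrees of freedom. A letter (A, B or C, 8 arrays each) in the sample names was presumed to mark the chip batch. Signal cannot be set against background, since no detection calls were used here.

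The file held 45101 probe sets. The platform annotation gave 34958 of them 1 gene symbol, 932 several and 9211 none, and 34754 of the first kind matched a mouse RefSeq gene by Entrez identifier. RefSeq of assembly GRCm38.p6 served only for names and for the order of neighbouring genes. For each gene the probe set with the highest mean was used, which left 18194 genes, 9012 of them with more than 1 probe set. Probe sets without a single symbol were left out of gene tests and examined apart.

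Differences were tested with limma 3.58.1 in R 4.3.3, with means of the 12 groups and the letter as a fixed effect in 1 fit of all 24 arrays, empirical Bayes moderation (10 residual and 3.04 prior degrees of freedom) and Benjamini-Hochberg adjustment within each comparison. The comparisons were the infection response in each cell type and genotype, its interaction with genotype, WT minus IFNAR-KO in uninfected and infected mice, the cell types in uninfected WT mice and the differences of WT responses. Except where the text names a later choice, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Names were drawn from the 8 largest changes in each direction among called genes whose replicates did not overlap, up to 4 members of each list past its test, marker genes by level, and Ifnar1, Ifng, Il12b and Il15. Interactions and differences of responses had no overlap condition, and predicted genes were skipped.

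The 35 gene lists, of pathways, cell type markers and neighbours of Ifnar1 and Ptprc on their chromosomes, came from textbook knowledge. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists within a comparison. List tests of the cell type comparisons and differences of responses were added after the data were seen. The software also included the data.table package, version 1.17.8, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

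Replicates of a group were compared over all probe sets, with Pearson correlations from 0.957 to 0.993, SDs of the difference from 0.307 to 0.714 and 1 to 43 of 45101 values equal to the last deposited digit, so none was counted as a duplicate. Replicate numbers mark the spleen pool per the labels, shared by WT and IFNAR-KO cells of the same chimeras. Deviations of WT and IFNAR-KO cells from their group means correlated across genes at 0.27 to 0.685 in the 6 pairs, so the numbers were taken to pair the samples.

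The tests were tried on simulated data with 200 of 18194 genes changed. For the WT NK infection response, 60 of 100 genes changed 2-fold and 92 of 100 changed 4-fold were called, all with the right sign, with 11 of 17951 unchanged genes called. For the NK interaction, 29 and 67 were called and 4 unchanged genes. A shift of 1 of the type I IFN list in a WT NK response gave a camera adjusted p of 1.79e-44 and 0 other lists past. Correlated genes or shared pools were not tried.

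Alternatives were no letter term, the spleen pool as a block with the letter term, a fit of only the arrays of the compared cell types without the letter term, centring of each array on its median, a trended robust prior, only genes brighter than the median probe set, the mean of a gene's probe sets, and each array left out in turn. With 1 array left out, the remaining array of its group was assumed to vary like the other groups. The largest median change over all genes in a comparison was 0.0345.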

Results

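Gene expression was measured on 24 Affymetrix arrays of cells sorted from mouse spleen. The mice were mixed bone marrow chimeras, in which CD45.1 wild-type (WT) cells and CD45.2 cells lacking the type I interferon receptor (IFNAR-KO) develop side by side in the same animals. Natural killer (NK) cells, CD8a+ dendritic cells (DC) and CD11b+ DC were taken from uninfected mice and from mice 36 h after infection with murine cytomegalovirus (MCMV), a herpesvirus. NK cells were sorted as NKp46-positive, and DC as NKp46-negative and CD11c-high, with the CD11b+ subset gated as CD8a-negative. Each of the 12 groups of genotype, cell type and infection state had 2 arrays, from separate pools of 5 to 8 mice. The number of arrays limits the precision, and WT and IFNAR-KO cells of 1 replicate number came from the same pool. Replicate 1 of infected WT NK cells was labelled from 8 ng of RNA and all other arrays from 50 ng. That group's replicates correlated least (0.957). Principal component 1 (49.6% of the variance) parted NK cells from DC, and component 2 (13.1%) the DC subsets.

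Changes below are log2 differences ± SE from limma, with 2 arrays per group, and genes rose, fell or differed where the adjusted p was under 0.05. All p-values rest on the spread between 2 spleen pools per infection state, and infected and uninfected pools were different mice. Second counts of a list, given as over it alone, were adjusted over that list only. List calls held with an estimated correlation where no such p, adjusted over all lists too, stands beside them. The largest changes were named only where replicates did not overlap. Values within the letter, the presumed chip batch, compare 1 array with 1 where a letter held both groups. Each sets replicate 1 against 2, so different pools. No letter held every group of an interaction, a response difference or the comparison of NK cells with both DC subsets.

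Ifnar1, the disrupted gene, was read by 2 probe sets. The brighter probe set stood in uninfected WT and IFNAR-KO cells at 7.83 ± 0.18 and 8.36 ± 0.74 (SD, n = 2) in NK cells, 7.66 ± 0.14 and 7.41 ± 0.16 in CD8a+ DC, and 7.63 ± 0.08 and 8.26 ± 0.10 in CD11b+ DC. In infected mice the values were 7.19 ± 0.19 and 7.22 ± 0.05, 7.96 ± 0.03 and 7.30 ± 0.33, and 6.92 ± 0.75 and 7.82 ± 0.08. Averaged over the 6 pairs of groups, WT minus IFNAR-KO was -0.20 ± 0.12 (limma adjusted p = 0.582), and -0.026 with both probe sets averaged. In uninfected and infected mice it was 0.39 and 0.53 in CD8a+ DC and -0.77 and -0.92 in CD11b+ DC. The dimmer probe set differed by -0.78 to 1.52 over these pairs, with the highest value in infected CD8a+ DC. A 3-prime probe set can lie outside the disrupted part of a gene, in which case it checks nothing about the labels.

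Genes of chemokines, cytokines and the interferon response were among the largest rises in infected WT NK cells. The chemokine gene Cxcl10 rose by 6.98 ± 0.25, the DNA-sensor family gene Ifi204 (5.83 ± 0.31) and the antiviral restriction factor Ifitm3 (5.00 ± 0.53) rose, and so did Ifi27l2a (5.64 ± 0.46) and Slfn4 (5.99 ± 1.05). The cytokine and chemokine genes Il6 (5.48 ± 0.56), Cxcl2 (5.19 ± 0.56) and Il10 (4.85 ± 0.34) also rose. Among the genes that fell were S1pr1 (the receptor for egress from lymphoid tissue, -4.26 ± 0.58), Cmah (an enzyme of sialic acid modification, -5.00 ± 0.61), Scd2 (a fatty acid desaturase, -4.21 ± 0.30) and Foxo3 (a transcription factor of quiescence, -3.76 ± 0.51), with Tcp11l2 (-4.33 ± 0.56) and Mxd4 (-3.90 ± 0.31). In all 643 genes rose and 1118 fell, 433 and 811 of them by at least 2-fold. Of the type I IFN-stimulated genes, 30 of 43 rose and 1 fell, 37 and 1 over it alone; Isg20 (4.70 ± 0.46), Usp18 (4.56 ± 0.20) and Rsad2 (4.21 ± 0.31) were among the highest. The median was 1.58 (1.42 within the letter, camera adjusted p = 1.15e-32). Among the IFN-gamma-associated GTPases and chemokines, 7 of 20 rose and 0 fell, 9 and 0 over it alone, with Iigp1 (4.48 ± 0.78), Gbp6 (3.16 ± 0.42) and Igtp (1.99 ± 0.24). The median was 0.68 (0.87 within the letter, camera adjusted p = 2.48e-08). In the ribosome biogenesis list 9 of 26 rose and 0 fell, 15 and 0 over it alone, with the polyamine enzymes Srm (2.58 ± 0.31) and Odc1 (1.74 ± 0.19) and the nucleolar gene Nop16 (1.92 ± 0.33). The median was 0.72 (1.00 within the letter, camera adjusted p = 6.57e-10, p = 0.146 with an estimated correlation). For cell cycle and DNA replication 5 of 33 rose and 0 fell, 7 and 0 over it alone, and the replication-licensing genes Mcm3 (1.54 ± 0.30) and Cdc6 (1.52 ± 0.32) rose. The median was 0.57 (1.39 within the letter, camera adjusted p = 7.05e-06, p = 0.467 with an estimated correlation). Of the NF-kB targets 8 of 18 rose and 0 fell, 12 and 0 over it alone, led by Gadd45b (3.51 ± 0.44), Bcl3 (2.31 ± 0.31) and Nfkb2 (1.98 ± 0.43). The median was 0.96 (0.82 within the letter, camera adjusted p = 1.21e-08, p = 0.219 with an estimated correlation). For cytokine receptors and STAT-SOCS signalling 8 of 24 rose and 1 fell, 10 and 1 over it alone, with Il2ra (the high-affinity IL-2 receptor chain, 3.23 ± 0.33), Socs3 (2.70 ± 0.46) and Cish (2.24 ± 0.38). The median was 0.49 (0.29 within the letter, camera adjusted p = 0.00168, p = 0.406 with an estimated correlation). The trafficking receptors moved down, as 2 of 21 rose and 8 fell, 2 and 9 over it alone, with Cxcr3 (-2.79 ± 0.36) and Itgam (-2.66 ± 0.48) lower and the activation marker Cd69 (2.53 ± 0.42) higher. The median was -0.73 (-0.58 within the letter, camera adjusted p = 0.00129, p = 0.219 with an estimated correlation). Of the NK effector molecules 5 of 19 rose and 0 fell, 5 and 2 over it alone; Gzmc (3.36 ± 0.42) and Csf2 (2.14 ± 0.53) rose. The median was 0.50 (0.74 within the letter, camera adjusted p = 0.011, p = 0.422 with an estimated correlation). The unfolded protein response list moved up as well, and 6 of 20 rose and 0 fell, 9 and 1 over it alone, with Asns (2.01 ± 0.33), Sdf2l1 (1.53 ± 0.26) and Manf (1.44 ± 0.21). The median was 0.47 (0.60 within the letter, camera adjusted p = 1.79e-04, p = 0.233 with an estimated correlation). Inflammatory cytokines and chemokines moved up, and 5 of 25 rose and 0 fell, 5 and 0 over it alone. The median was 0.35 (0.17 within the letter, camera adjusted p = 2.55e-06, p = 0.181 with an estimated correlation). Among markers of other cells, those of plasmacytoid DC (3 of 12 up, 0 down, median 0.16, camera adjusted p = 0.0362, p = 0.357 with an estimated correlation) and neutrophils (0 of 14 called, median 0.23, camera adjusted p = 0.0399, p = 0.422 with an estimated correlation) passed, and so did immediate-early and dissociation stress genes (2 of 21 up, 0 down, median 0.33, camera adjusted p = 0.0206, p = 0.513 with an estimated correlation). Ifng went from 11.96 ± 0.24 to 14.22 ± 0.10 (SD, n = 2), and its change of 2.41 ± 1.30 (adjusted p = 0.295) did not pass in the fit of all arrays. Ifng was the brightest gene on all 4 infected NK arrays, so its level and change there may be understated. In a fit of the NK arrays alone the same change was 2.27 (adjusted p = 0.009), and over all alternatives the adjusted p ran from 0.009 to 0.675. The count was 2694 with the pool block and 218 in a fit of the compared cell types alone. It was 782 and 3856 without infected replicate 1 or 2 and 436 (219 up, 217 down) and 1048 without uninfected replicate 1 or 2. The first of these left-out arrays is the one labelled from 8 ng, and 673 of the 1761 genes were called without it too.

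CD8a+ DC, the subset specialised in cross-presentation, responded in WT cells with the antiviral genes Ifit1 (6.13 ± 0.54) and Oasl2 (5.47 ± 0.32) and the PYHIN family genes Ifi213 (6.06 ± 0.33) and Ifi204 (5.88 ± 0.31), all of which rose. The cytokine gene Il12b (a subunit of IL-12, 2.75 ± 0.28) rose, as did Il6 (4.15 ± 0.56), Cxcl11 (3.70 ± 0.54) and Il15 (a cytokine that sustains NK cells, 1.83 ± 0.29). Lower were Hepacam2 (-6.11 ± 0.81), Lyz1 (a lysozyme, -4.09 ± 0.72), Lyz2 (-4.06 ± 0.62), Igsf6 (-3.78 ± 0.48), Itga8 (-3.73 ± 0.44) and Map2k6 (-3.42 ± 0.31). 450 genes rose and 547 fell, 368 and 377 by at least 2-fold. For type I IFN-stimulated genes 40 of 43 rose and 0 fell, 42 and 0 over it alone, with Rsad2 (4.90 ± 0.31) and Cmpk2 (4.84 ± 0.51). The median was 2.98 (2.69 within the letter, camera adjusted p = 6.1e-68). In the IFN-gamma-associated list 12 of 20 rose and 1 fell, 13 and 1 over it alone, led by Gbp2 (4.21 ± 0.43), Cxcl10 (4.18 ± 0.25) and Gbp7 (4.13 ± 0.67). The median was 1.64 (1.71 within the letter, camera adjusted p = 6.33e-15). Of the maturation and costimulation genes 15 of 27 rose and 0 fell, 19 and 0 over it alone, including Ccr7 (the homing receptor of maturing DC, 3.01 ± 0.33), Cd274 (2.68 ± 0.31), Tnfsf9 (2.49 ± 0.49) and Cd40 (2.41 ± 0.26). The median was 1.54 (0.89 within the letter, camera adjusted p = 1.67e-19, p = 0.0566 with an estimated correlation). Among inflammatory cytokines and chemokines 10 of 25 rose and 0 fell, 13 and 0 over it alone. The median was 1.14 (0.99 within the letter, camera adjusted p = 1.01e-11). In the NF-kB list 5 of 18 rose and 0 fell, 11 and 0 over it alone, with Relb (1.58 ± 0.39) and Traf1 (1.42 ± 0.27). The median was 0.88 (0.60 within the letter, camera adjusted p = 1.07e-09, p = 0.0955 with an estimated correlation). Of the apoptosis regulators 3 of 18 rose and 1 fell, 5 and 1 over it alone, among them the inflammatory caspase Casp4 (2.87 ± 0.23) and Mlkl (1.12 ± 0.27). The median was 0.44 (0.24 within the letter, camera adjusted p = 0.00179, p = 0.0955 with an estimated correlation). The cholesterol synthesis list moved down, with 0 of 17 rising and 3 falling, 0 and 9 over it alone, including Msmo1 (-2.17 ± 0.27), Stard4 (-1.28 ± 0.28) and Mvd (-1.25 ± 0.32). The median was -0.87 (-0.78 within the letter, camera adjusted p = 2.01e-06, p = 0.0955 with an estimated correlation). Of the NK effector molecules 7 of 19 rose and 0 fell, 13 and 1 over it alone; Ifng (6.57 ± 1.30) and Gzmb (5.28 ± 1.37) rose. The median was 1.53 (0.73 within the letter, camera adjusted p = 1.69e-09, p = 0.0746 with an estimated correlation). The NK cell marker list moved with them, as 1 of 14 rose and 0 fell, 1 and 0 over it alone. The median was 0.84 (0.09 within the letter, camera adjusted p = 0.00462, p = 0.51 with an estimated correlation). The median NK marker stood at 5.01% in replicate 1 and 1.35% in replicate 2 of its level in infected WT NK cells. Other markers past the test were those of plasmacytoid DC (4 of 12 up, 1 down, median 0.45, camera adjusted p = 0.0156, p = 0.205 with an estimated correlation), T cells (0 of 11 up, 1 down, median 0.50, camera adjusted p = 0.0476, p = 0.51 with an estimated correlation) and neutrophils (0 of 14 called, median 0.15, camera adjusted p = 0.0357, p = 0.405 with an estimated correlation). The actin 3-prime minus 5-prime difference, a sign of RNA quality, was 2.68 in infected replicate 1, the highest of all arrays, and 1.35 in replicate 2. The count was 726 (371 up, 355 down) without the batch term, 1799 with the pool block and 456 (228 up, 228 down) in a fit of the compared cell types alone. It was 371 (234 up, 137 down) and 1572 without infected replicate 1 or 2 and 404 (260 up, 144 down) and 369 (210 up, 159 down) without uninfected replicate 1 or 2.

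In WT CD11b+ DC the IL-12 subunit gene Il12b (5.19 ± 0.28) and the NK-sustaining cytokine gene Il15 (3.51 ± 0.29) rose, together with Slfn4 (7.86 ± 1.05), Cxcl10 (5.66 ± 0.25), Il6 (5.37 ± 0.56) and Cxcl11 (5.22 ± 0.54). The immunity-related GTPase gene Iigp1 (6.29 ± 0.78) and Rilpl1 (5.62 ± 0.58) rose too. Genes that fell included Mmp12 (macrophage elastase, -4.81 ± 0.45), Cd209a (a C-type lectin, -3.22 ± 0.41), Abca9 (-3.45 ± 0.29), Ramp1 (-3.31 ± 0.52), Col17a1 (-2.95 ± 0.23) and Mxd4 (-2.78 ± 0.31). 527 genes rose and 904 fell, 418 and 535 by at least 2-fold. Type I IFN-stimulated genes moved up, and 40 of 43 rose and 0 fell, 42 and 0 over it alone, with Cmpk2 (4.70 ± 0.51), Oasl1 (4.63 ± 0.30) and Oas3 (3.73 ± 0.24). The median was 2.13 (2.47 within the letter, camera adjusted p = 2.56e-53). Of the IFN-gamma-associated genes 15 of 20 rose and 1 fell, 16 and 1 over it alone, with Gbp6 (4.36 ± 0.42). The median was 1.83 (1.96 within the letter, camera adjusted p = 7.58e-19). For cytokines and chemokines 10 of 25 rose and 0 fell, 12 and 0 over it alone. The median was 1.22 (0.94 within the letter, camera adjusted p = 1.83e-14). In the maturation list 9 of 27 rose and 0 fell, 12 and 0 over it alone, with Cd86 (3.02 ± 0.35), Cd200 (3.06 ± 0.60) and Ccr7 (2.39 ± 0.33). The median was 0.97 (0.67 within the letter, camera adjusted p = 3.77e-09, p = 0.197 with an estimated correlation). MHC class I processing genes moved up, and 4 of 17 rose and 0 fell, 4 and 0 over it alone, with the transactivator Nlrc5 (1.73 ± 0.21) and the peptide transporter Tap1 (0.94 ± 0.14). The median was 0.34 (0.65 within the letter, camera adjusted p = 9.04e-05). MHC class II genes moved down, and 0 of 14 rose and 2 fell, 0 and 5 over it alone, with H2-Ob (-1.40 ± 0.39) and Ciita (-1.39 ± 0.39). The median was -0.48 (-0.36 within the letter, camera adjusted p = 0.0192, p = 0.37 with an estimated correlation). With them passed the markers of B cells (0 of 13 up, 2 down, median -0.60, camera adjusted p = 0.00433, p = 0.0534 with an estimated correlation) and plasmacytoid DC (2 of 12 up, 0 down, median 0.20, camera adjusted p = 0.0193, p = 0.259 with an estimated correlation). Of the apoptosis regulators 7 of 18 rose and 1 fell, 10 and 1 over it alone, including Casp4 (2.96 ± 0.23), Bcl2l11 (2.04 ± 0.37) and Cflar (1.54 ± 0.28). The median was 0.78 (0.71 within the letter, camera adjusted p = 8.84e-05, p = 0.0534 with an estimated correlation). Of the markers of this subset itself 1 of 18 rose and 7 fell, 2 and 10 over it alone. The median was -0.95 (-0.90 within the letter, camera adjusted p = 2.79e-04, p = 0.206 with an estimated correlation). Ribosome biogenesis genes moved down too: 1 of 26 rose and 2 fell, 1 and 8 over it alone. The median was -0.54 (-0.43 within the letter, camera adjusted p = 3.45e-04, p = 0.285 with an estimated correlation). Of the NK effector molecules 7 of 19 rose and 0 fell, 9 and 1 over it alone, with Ifng (6.22 ± 1.30), Gzmb (5.13 ± 1.37) and Tnfsf10 (3.11 ± 0.77). The median was 1.18 (0.72 within the letter, camera adjusted p = 7e-08, p = 0.0868 with an estimated correlation). Beside these, of the NK cell markers 2 of 14 rose and 0 fell, 2 and 0 over it alone. The median was 1.18 (0.23 within the letter, camera adjusted p = 4.38e-04, p = 0.375 with an estimated correlation). The median NK marker stood at 11.5% in replicate 1 and 5.4% in replicate 2 of the level in infected WT NK cells. Leaving out 1 array gave 399 (257 up, 142 down) without infected replicate 1 and 352 (224 up, 128 down) and 568 (303 up, 265 down) without uninfected replicate 1 or 2.

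The WT responses overlapped between cell types. 106 genes rose in all 3 and 82 fell in all 3, against 0.461 and 1.67 for independent lists of these sizes. Of the 106, 27 belonged to the type I IFN-stimulated list. CD8a+ DC and CD11b+ DC shared 286 genes that rose (13 for independent lists) and 241 that fell (27.2). The cell types of 1 replicate came from the same spleen pools, so part of the excess may come from the pools.

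**Figure D1:**
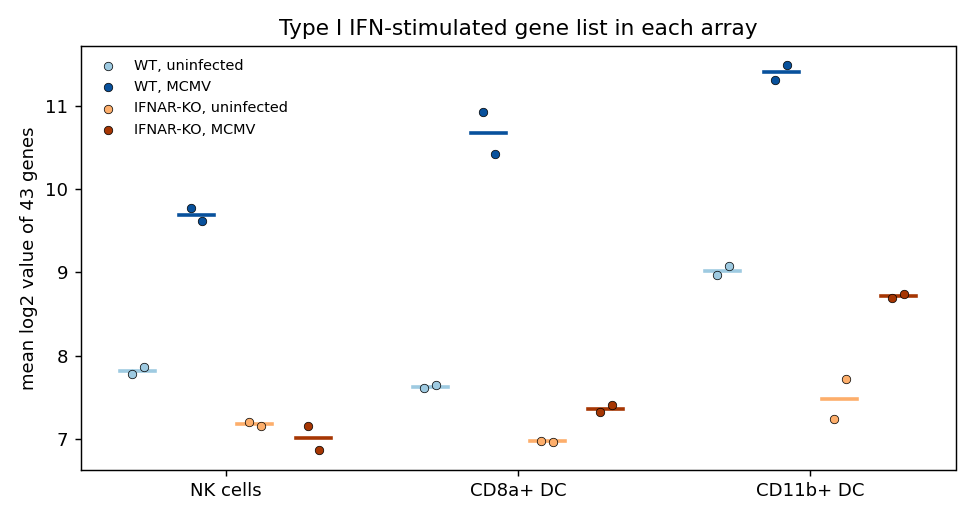
Mean log2 value of the 43 measured type I IFN-stimulated genes in each array (points) and the group mean (bars), by cell type, genotype and infection state. WT means went from 7.82 to 9.69 in NK cells, 7.63 to 10.67 in CD8a+ DC and 9.02 to 11.40 in CD11b+ DC, and IFNAR-KO means from 7.18 to 7.01, 6.97 to 7.36 and 7.48 to 8.72.

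IFNAR-KO cells of the same mice show which changes occurred without a functional receptor for type I interferon on the responding cell. In IFNAR-KO NK cells Prnp (the prion protein gene, 5.92 ± 0.62), Cxcl2 (5.34 ± 0.56), Cxcl10 (5.28 ± 0.25) and Il10 (4.65 ± 0.34) rose, as did the inhibitory receptor gene Ctla4 (4.30 ± 0.81) and Kctd14 (4.90 ± 0.34) and Ifitm1 (4.80 ± 0.62). Lower were Cmah (-3.44 ± 0.61), Klhl24 (-3.56 ± 0.53), Angpt1 (-3.34 ± 0.32), Cd1d1 (an antigen-presenting molecule for NKT cells, -3.32 ± 0.36) and Gprin3 (-3.29 ± 0.32). 549 genes rose and 663 fell, 363 and 480 by at least 2-fold. Of the type I IFN-stimulated genes 2 of 43 rose and 7 fell, 3 and 9 over it alone; Usp18 (2.80 ± 0.20) and Rsad2 (1.84 ± 0.31) rose and Cmpk2 (-2.31 ± 0.51) fell. The median was -0.26 (-0.29 within the letter, camera adjusted p = 0.00873, p = 0.391 with an estimated correlation). Ribosome biogenesis genes moved up, and 13 of 26 rose and 0 fell, 16 and 0 over it alone, with Srm (2.58 ± 0.31), Nop16 (2.11 ± 0.33) and Nop56 (1.62 ± 0.24). The median was 0.85 (0.99 within the letter, camera adjusted p = 1.88e-14, p = 0.139 with an estimated correlation). In the cell cycle list 7 of 33 rose and 0 fell, 15 and 0 over it alone, with Mcm3 (1.57 ± 0.30) and Gins1 (1.47 ± 0.28). The median was 1.01 (1.66 within the letter, camera adjusted p = 4.8e-11, p = 0.352 with an estimated correlation). Of the NF-kB targets 8 of 18 rose and 0 fell, 11 and 0 over it alone, led by Gadd45b (2.94 ± 0.44). The median was 1.21 (0.92 within the letter, camera adjusted p = 1.44e-09, p = 0.222 with an estimated correlation). In the cytokine receptor and STAT-SOCS list 7 of 24 rose and 1 fell, 8 and 1 over it alone, with Il2ra (3.60 ± 0.33) and Myc (1.78 ± 0.41). The median was 0.34 (-0.05 within the letter, camera adjusted p = 0.00813, p = 0.421 with an estimated correlation). For the unfolded protein response 9 of 20 rose and 0 fell, 10 and 0 over it alone, with Asns (1.73 ± 0.33) and Creld2 (1.49 ± 0.24). The median was 0.76 (0.61 within the letter, camera adjusted p = 3.96e-06, p = 0.222 with an estimated correlation). Trafficking receptors moved down, and 2 of 21 rose and 6 fell, 2 and 9 over it alone, including S1pr1 (-3.19 ± 0.58) and Cxcr3 (-2.63 ± 0.36). The median was -0.65 (-0.81 within the letter, camera adjusted p = 0.00289, p = 0.269 with an estimated correlation). Markers of other cells that passed were those of T cells (0 of 11 up, 2 down, median -0.77, camera adjusted p = 0.00664, p = 0.382 with an estimated correlation), B cells (0 of 13 up, 2 down, median -0.18, camera adjusted p = 0.0249, p = 0.222 with an estimated correlation) and neutrophils (0 of 14 called, median 0.30, camera adjusted p = 0.0167, p = 0.382 with an estimated correlation). Of the effector molecules 4 of 19 rose and 0 fell, 4 and 0 over it alone, with Csf2 (3.32 ± 0.53) and Gzmc (3.16 ± 0.42). The median was 0.58 (0.30 within the letter, camera adjusted p = 0.00813, p = 0.391 with an estimated correlation). Ifng went from 12.41 ± 0.02 to 14.33 ± 0.07 (SD, n = 2), a change of 2.10 ± 1.30 (adjusted p = 0.433), which was 1.92 (adjusted p = 0.0158) in a fit of the NK arrays alone and may be understated too. For cytokines and chemokines 6 of 25 rose and 0 fell, 6 and 0 over it alone. The median was 0.55 (0.35 within the letter, camera adjusted p = 3.45e-04, p = 0.269 with an estimated correlation). Ifnar1 itself fell by 1.28 ± 0.31. The count was 1836 with the pool block and 132 (72 up, 60 down) in a fit of the compared cell types alone. It was 724 without infected replicate 1 and 377 (193 up, 184 down) and 778 without uninfected replicate 1 or 2.

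In IFNAR-KO CD8a+ DC the GTPase genes Iigp1 (4.10 ± 0.78), Gbp2 (4.01 ± 0.43) and Gbp7 (3.64 ± 0.67), the cyclin gene Ccnd2 (5.08 ± 0.52) and the IL-12 subunit gene Il12b (3.24 ± 0.28) rose. Hepacam2 (-4.10 ± 0.81), Map2k6 (-3.08 ± 0.31), Itga8 (-3.07 ± 0.44), Fbxo32 (a ubiquitin ligase subunit, -2.86 ± 0.40) and Igsf6 (-2.45 ± 0.48) fell. 134 genes rose and 72 fell, 117 and 60 by at least 2-fold. Of the IFN-gamma-associated list 11 of 20 rose and 0 fell, 14 and 0 over it alone. The median was 1.68 (1.42 within the letter, camera adjusted p = 2.86e-27). In the type I IFN-stimulated list 4 of 43 rose and 1 fell, 10 and 1 over it alone, with Oasl2 (2.18 ± 0.32), Slfn5 (2.04 ± 0.35) and Herc6 (1.85 ± 0.26). The median was 0.29 (0.24 within the letter, camera adjusted p = 2.88e-06, p = 0.105 with an estimated correlation). Maturation genes moved up, and 9 of 27 rose and 0 fell, 14 and 0 over it alone, with Pdcd1lg2 (3.16 ± 0.28), Cd274 (3.08 ± 0.31) and Ccr7 (2.60 ± 0.33). The median was 1.39 (0.79 within the letter, camera adjusted p = 2.82e-25). For cytokines and chemokines 6 of 25 rose and 0 fell, 12 and 0 over it alone, including Cxcl2 (4.53 ± 0.56), Cxcl10 (3.37 ± 0.25) and Il6 (2.87 ± 0.56). The median was 0.97 (0.98 within the letter, camera adjusted p = 2.33e-18). Of the receptor and STAT-SOCS list 5 of 24 rose and 0 fell, 8 and 0 over it alone, with Socs3 (3.70 ± 0.46), Stat4 (2.89 ± 0.55) and Tbx21 (2.48 ± 0.44). The median was 0.53 (0.33 within the letter, camera adjusted p = 1.51e-11). In the apoptosis list 3 of 18 rose and 0 fell, 4 and 0 over it alone, with Casp4 (2.62 ± 0.23) and Casp8 (1.57 ± 0.26). The median was 0.15 (0.12 within the letter, camera adjusted p = 2.9e-04, p = 0.0604 with an estimated correlation). Il15, by contrast, had a change of 0.37 ± 0.29 (adjusted p = 0.804). Ifng (7.05 ± 1.30) rose, and among the NK effector molecules 3 of 19 rose and 0 fell, 10 and 0 over it alone. The median was 1.26 (0.88 within the letter, camera adjusted p = 1.78e-11). Of the NK cell markers, which moved with them, 1 of 14 rose and 0 fell, 1 and 0 over it alone. The median was 0.87 (0.17 within the letter, camera adjusted p = 0.00207, p = 0.488 with an estimated correlation). Their median stood at 3.98% in replicate 1 and 1.26% in replicate 2 of the level in infected IFNAR-KO NK cells. B cell markers moved down: 0 of 13 rose and 2 fell, 0 and 5 over it alone. The median was -0.36 (-0.35 within the letter, camera adjusted p = 4.85e-05). Others past the test were markers of CD11b+ DC (0 of 18 up, 2 down, median -0.53, camera adjusted p = 6.2e-06, p = 0.0994 with an estimated correlation) and monocytes (0 of 11 called, median -0.23, camera adjusted p = 0.0283, p = 0.283 with an estimated correlation). The count was 368 with the pool block and 11 in a fit of the compared cell types alone. It was 114 and 73 without infected replicate 1 or 2 and 113 and 97 without uninfected replicate 1 or 2.

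IFNAR-KO CD11b+ DC raised Il12b (6.45 ± 0.28), Il6 (6.28 ± 0.56), Cxcl2 (5.30 ± 0.56) and Cxcl10 (5.15 ± 0.25) and the lectin gene Clec4e (5.88 ± 0.52). The uridine phosphorylase gene Upp1 (5.35 ± 0.46) rose too. Mmp12 (-4.01 ± 0.45), Abca9 (-3.56 ± 0.29), Cd209a (-3.25 ± 0.41), Mmp9 (a matrix metalloproteinase, -2.67 ± 0.18) and Clec4g (-2.63 ± 0.21) fell. 330 genes rose and 243 fell, 290 and 190 by at least 2-fold. Of the type I IFN-stimulated genes 18 of 43 rose and 0 fell, 31 and 0 over it alone, with Oasl2 (4.27 ± 0.32), Rtp4 (3.75 ± 0.54) and Ifit1 (3.49 ± 0.54). The median was 1.15 (1.30 within the letter, camera adjusted p = 1.6e-29). In the IFN-gamma-associated list 15 of 20 rose and 0 fell, 16 and 0 over it alone, with Iigp1 (5.58 ± 0.78) and Gbp2 (4.24 ± 0.43). The median was 1.98 (2.23 within the letter, camera adjusted p = 1.6e-29). For cytokines and chemokines 13 of 25 rose and 0 fell, 16 and 0 over it alone. The median was 1.49 (1.48 within the letter, camera adjusted p = 2.65e-25). Of the maturation genes 10 of 27 rose and 0 fell, 18 and 0 over it alone, with the chemokine genes Ccl22 (3.72 ± 0.43) and Ccl17 (3.47 ± 0.41) and Ccr7 (3.20 ± 0.33). The median was 1.34 (1.06 within the letter, camera adjusted p = 2.49e-17). MHC class I processing genes moved up, and 3 of 17 rose and 0 fell, 5 and 0 over it alone. The median was 0.60 (0.56 within the letter, camera adjusted p = 2.82e-07). In the glycolysis list 2 of 18 rose and 0 fell, 3 and 1 over it alone, with Pfkp (2.30 ± 0.22) and Slc2a1 (a glucose transporter, 1.71 ± 0.24). The median was 0.30 (0.22 within the letter, camera adjusted p = 0.00296, p = 0.144 with an estimated correlation). For the NF-kB targets 2 of 18 rose and 0 fell, 8 and 0 over it alone, with Tnfaip2 (3.70 ± 0.60). The median was 0.73 (0.71 within the letter, camera adjusted p = 2.49e-09, p = 0.0979 with an estimated correlation). Il15 had a change of 0.69 ± 0.29 (adjusted p = 0.344). Ifng (7.36 ± 1.30) and Serpinb9 (a granzyme inhibitor, 3.20 ± 0.19) rose, and of the NK effector molecules 4 of 19 rose and 0 fell, 7 and 0 over it alone. The median was 0.93 (0.55 within the letter, camera adjusted p = 8.95e-10). Of the NK cell markers 1 of 14 rose and 0 fell, 1 and 0 over it alone. The median was 1.22 (0.02 within the letter, camera adjusted p = 3.76e-05, p = 0.264 with an estimated correlation). Their median stood at 7.73% in replicate 1 and 4.43% in replicate 2 of the level in infected IFNAR-KO NK cells. Of the markers of CD11b+ DC 0 of 18 rose and 6 fell, 0 and 6 over it alone. The median was -0.69 (-0.91 within the letter, camera adjusted p = 2.32e-07, p = 0.0552 with an estimated correlation). Among the monocyte markers 2 of 11 rose and 0 fell, 2 and 0 over it alone. The median was 0.30 (0.33 within the letter, camera adjusted p = 0.00346, p = 0.134 with an estimated correlation). Also past the test were markers of B cells (0 of 13 up, 2 down, median -0.52, camera adjusted p = 5.77e-06) and CD8a+ DC (2 of 16 up, 0 down, median 0.36, camera adjusted p = 0.0248, p = 0.49 with an estimated correlation). The count was 875 with the pool block. It was 252 (196 up, 56 down) and 296 without infected replicate 1 or 2 and 261 and 252 without uninfected replicate 1 or 2.

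Many genes called in WT cells were called in the same direction in IFNAR-KO cells. 344 of the 643 genes that rose in WT NK cells rose in IFNAR-KO NK cells, against 19.4 for independent lists, and 474 of 1118 fell in both, against 40.7. In CD8a+ DC 101 of 450 rose in both (3.31 for independent lists) and 53 of 547 fell in both (2.16). In CD11b+ DC the numbers were 195 of 527 (9.56) and 174 of 904 (12.1). Both genotypes shared their mouse pools, so part of the excess may come from the pools.

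**Figure D2:**
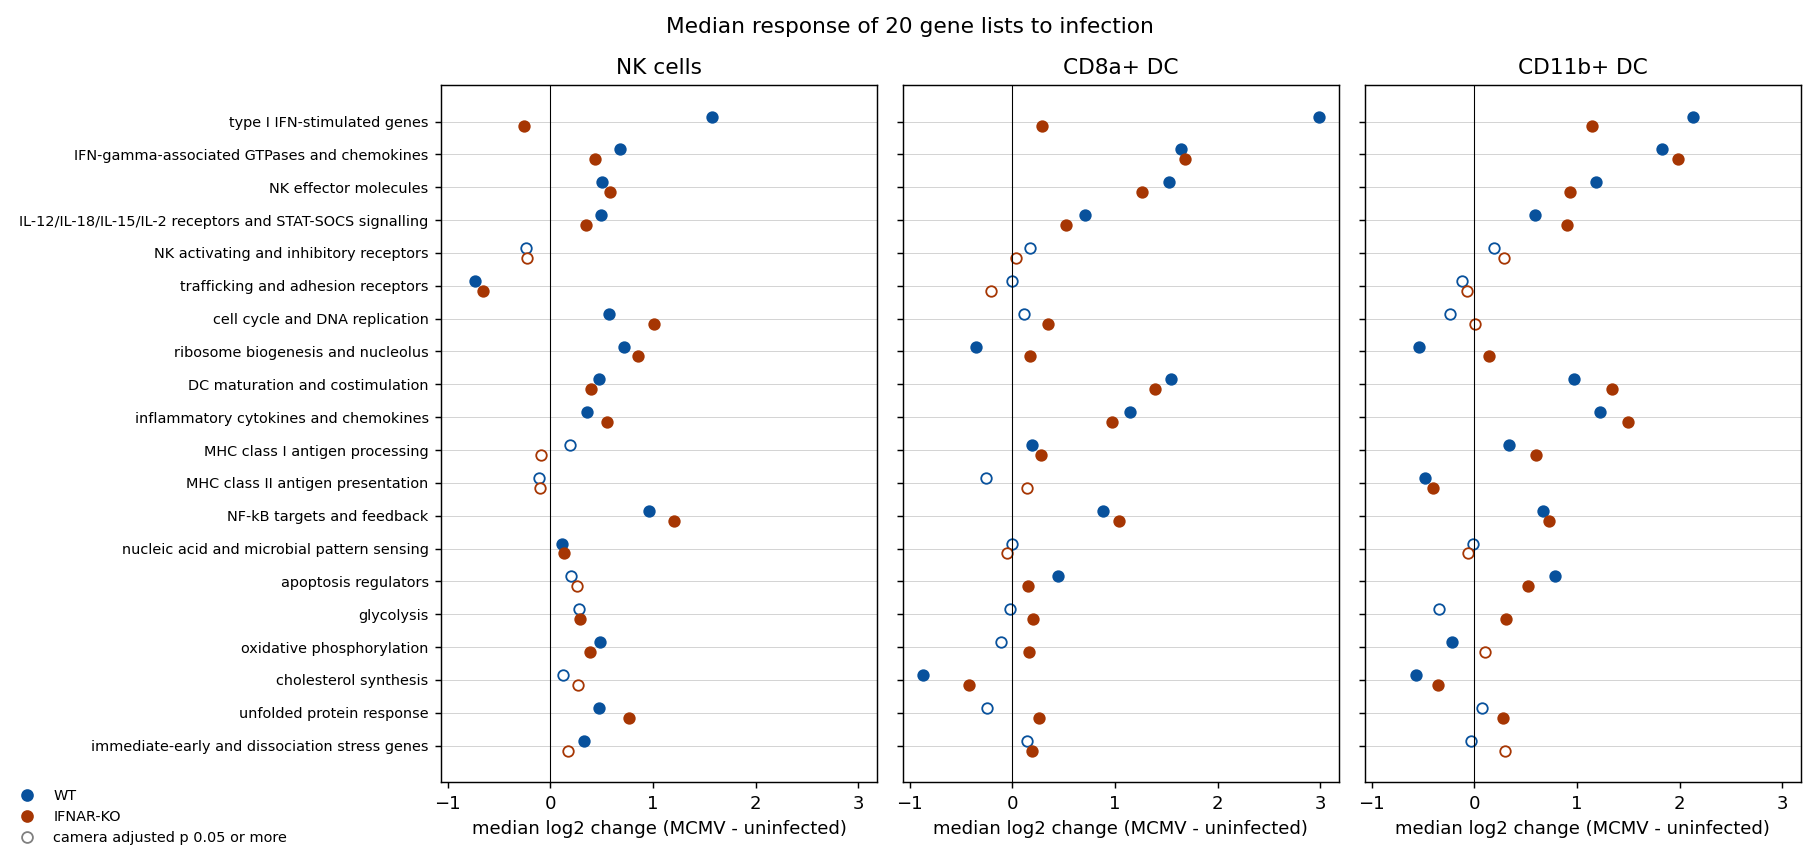
Median log2 change on infection of the 20 gene lists that are not cell type markers or chromosome neighbours, in WT and IFNAR-KO cells of each cell type. Filled points passed the camera test and open points did not; for the type I IFN-stimulated list the WT and IFNAR-KO medians were 1.58 and -0.26 in NK cells, 2.98 and 0.29 in CD8a+ DC, and 2.13 and 1.15 in CD11b+ DC.

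The interaction of genotype and infection tests which responses differed between WT and IFNAR-KO cells, with positive values for a larger WT response. In NK cells the antiviral GTPase gene Mx1 (4.60 ± 0.40), the exonuclease gene Isg20 (4.00 ± 0.66) and Ifi213 (4.99 ± 0.47), Ifi27l2a (4.92 ± 0.67), Ifi204 (4.63 ± 0.45), Oasl2 (3.38 ± 0.46) and Trim30d (3.00 ± 0.24) had larger responses in WT cells. 22 interactions were positive and 1 was negative, that of Armcx4 (-1.54 ± 0.23). Among type I IFN-stimulated genes 13 of 43 were higher and 0 lower, 37 and 0 over it alone. The median was 2.07 (camera adjusted p = 9.81e-100). In the IFN-gamma-associated list 0 of 20 were higher and 0 lower, 2 and 0 over it alone; Cxcl10 had a value of 1.70 ± 0.35 (adjusted p = 0.149). The median was 0.27 (camera adjusted p = 8.64e-05, p = 0.172 with an estimated correlation). For Il6 the difference was 2.65 ± 0.80 (adjusted p = 0.934). That of Ifng, 0.31 ± 1.87 (adjusted p = 1), shows nothing, as both infected groups were near the array maximum. Markers that passed were those of CD11b+ DC (0 of 18 called, median 0.30, camera adjusted p = 0.0227, p = 0.756 with an estimated correlation) and plasmacytoid DC (0 of 12 called, median 0.16, camera adjusted p = 0.0406, p = 0.547 with an estimated correlation). The count was 15 without the batch term and 0 in a fit of the compared cell types alone. It was 367 (100 up, 267 down) without infected WT replicate 2, 11 without uninfected WT replicate 1, 8 without infected IFNAR-KO replicate 2 and 8 and 9 without uninfected IFNAR-KO replicate 1 or 2. On the NK arrays alone, with 0 calls, 299 genes had an unadjusted limma p under 0.05, fewer than chance gives.

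In CD8a+ DC the oligoadenylate synthetase gene Oas1a (5.07 ± 0.45) and Ifi213 (6.33 ± 0.47), Ifit1 (4.69 ± 0.77), Ifit3 (4.58 ± 0.59), Rtp4 (4.54 ± 0.78) and Isg20 (4.49 ± 0.66) responded more strongly in WT cells. 51 interactions were positive and 2 were negative, Esyt2 (-1.33 ± 0.24) and Man1a2 (-1.18 ± 0.22). Among the type I IFN-stimulated genes 21 of 43 were higher and 0 lower, 35 and 0 over it alone. The median was 2.47 (camera adjusted p = 3.12e-70). The ribosome biogenesis list lay below 0, with 0 of 26 higher and 0 lower, 0 and 0 over it alone. The median was -0.58 (camera adjusted p = 3.16e-05, p = 0.75 with an estimated correlation). Il12b and Il15 had interactions of -0.49 ± 0.40 (adjusted p = 0.846) and 1.46 ± 0.42 (adjusted p = 0.343). The count was 11 in a fit of the compared cell types alone. It was 189 (126 up, 63 down) without infected WT replicate 2, 31 without uninfected WT replicate 1 and 27 without infected IFNAR-KO replicate 2.

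In CD11b+ DC the interaction was positive for the NK-sustaining cytokine gene Il15 (2.82 ± 0.42), which stood at 10.73 ± 0.07 in infected WT and 7.26 ± 0.41 in infected IFNAR-KO cells (SD, n = 2). Rilpl1 (4.88 ± 0.84), Ddx4 (4.39 ± 0.52), Oasl1 (3.65 ± 0.43), Oas3 (3.26 ± 0.34), Mx1 (3.12 ± 0.40) and Slfn3 (3.32 ± 0.56) were positive too. Negative interactions included Lpl (lipoprotein lipase, -4.12 ± 0.45), Bst1 (an ectoenzyme of NAD metabolism, -3.55 ± 0.51), Ifi27 (-3.56 ± 0.57), Vdr (the vitamin D receptor, -2.24 ± 0.37) and Ubd (-1.97 ± 0.29). In total 25 were positive and 17 negative. Of the type I IFN-stimulated genes 7 of 43 were higher and 0 lower, 23 and 2 over it alone. The median was 1.16 (camera adjusted p = 7.68e-26). Ribosome biogenesis genes lay below 0, with 0 of 26 higher and 0 lower, 0 and 1 over it alone. The median was -0.64 (camera adjusted p = 6.91e-09, p = 0.291 with an estimated correlation). Glycolysis genes did too, with 0 of 18 higher and 0 lower, 0 and 2 over it alone. The median was -0.56 (camera adjusted p = 0.00101, p = 0.311 with an estimated correlation). Il12b had an interaction of -1.26 ± 0.40 (adjusted p = 0.456). Of the monocyte markers 0 of 11 were higher and 0 lower, 0 and 0 over it alone. The median was -1.01 (camera adjusted p = 0.02, p = 0.51 with an estimated correlation). The count was 15 (12 up, 3 down) in a fit of the compared cell types alone and 23 (18 up, 5 down) over genes brighter than the median probe set. It was 23 and 74 (29 up, 45 down) without infected WT replicate 1 or 2, 9 and 21 (16 up, 5 down) without uninfected WT replicate 1 or 2, 18 and 33 (15 up, 18 down) without infected IFNAR-KO replicate 1 or 2 and 13 (10 up, 3 down) and 10 (8 up, 2 down) without uninfected IFNAR-KO replicate 1 or 2.

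5 genes had a positive interaction in all 3 cell types, namely Daxx, Mx1, Oas3, Oasl1 and Samd9l. 68 genes were positive in at least 1 cell type, and 23 of these were in the type I IFN-stimulated list. By cell type, 13 of 22 genes in NK cells, 21 of 51 in CD8a+ DC and 7 of 25 in CD11b+ DC belonged to it.

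**Figure D3:**
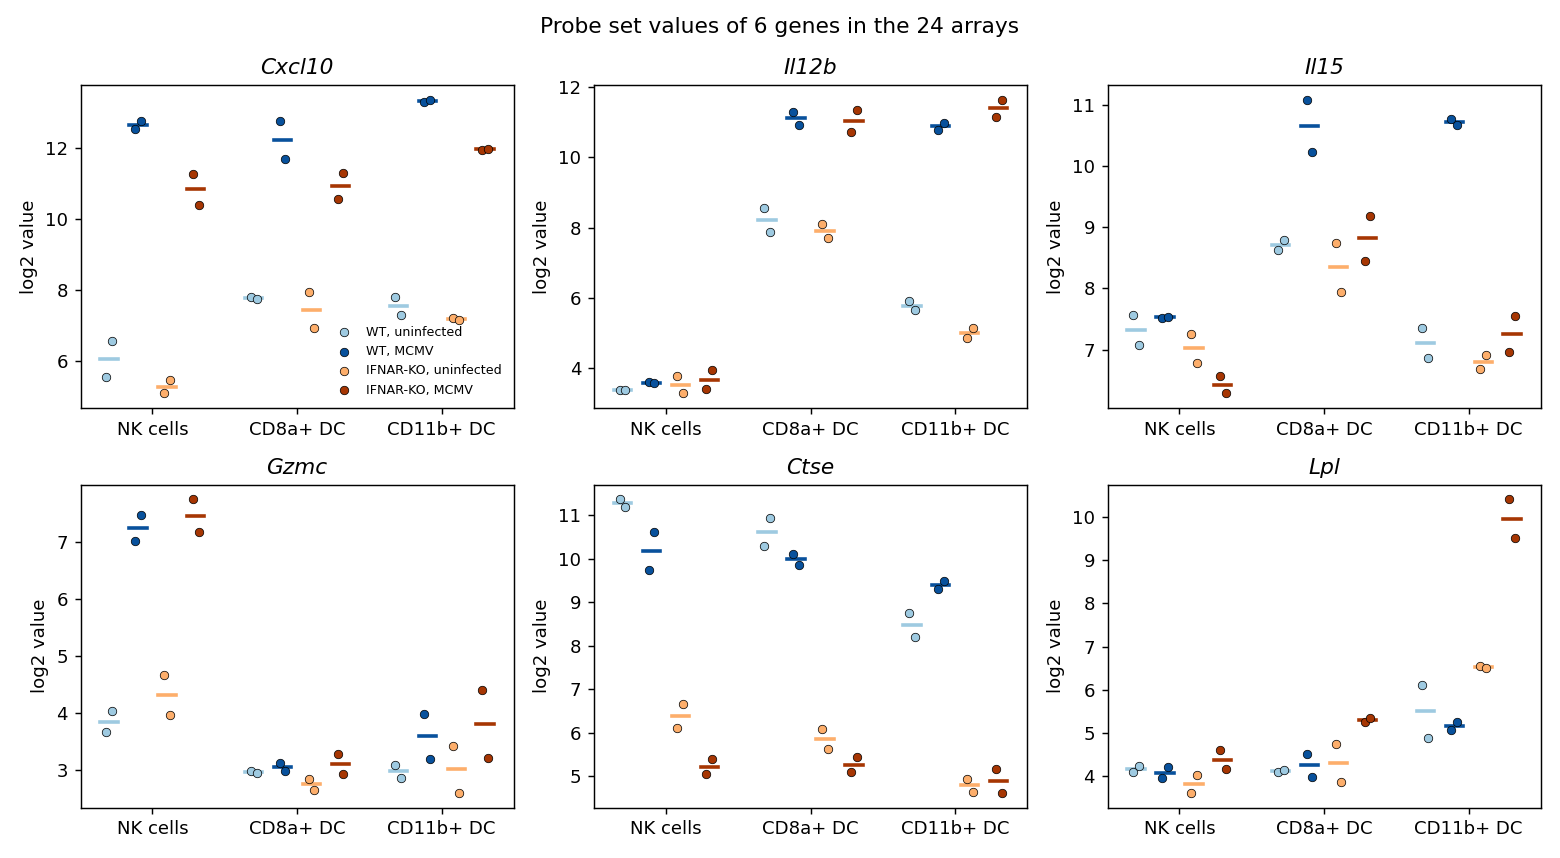
Log2 value of 6 genes in each array (points) with the group mean (bars), by cell type, genotype and infection state. Il15 in infected CD11b+ DC averaged 10.73 in WT and 7.26 in IFNAR-KO cells, Il12b 10.88 and 11.40, and Lpl 5.17 and 9.96.

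Without infection, WT and IFNAR-KO cells differed at few genes. In NK cells the 3 called genes, all higher in WT, were Ctse (cathepsin E, 4.75 ± 0.31), Oas1a (2.65 ± 0.31) and Usp18 (a negative regulator of interferon signalling, 2.55 ± 0.20). In CD8a+ DC Ctse (4.75 ± 0.31), Ifi207 (3.99 ± 0.41), Usp18 (2.74 ± 0.20), Ifit2 (1.97 ± 0.29) and Trim30d (1.20 ± 0.17) were higher in WT and Ppfia4 (-3.97 ± 0.29) and Cyp8b1 (-2.33 ± 0.27) lower, 5 and 2 genes in all. In CD11b+ DC 16 genes were higher in WT and 1 lower. The higher genes there included Oas1a (5.24 ± 0.31), Ifi27l2a (4.46 ± 0.46), Oasl2 (4.28 ± 0.32), Rtp4 (4.21 ± 0.54) and Ifit1 (4.00 ± 0.54), with Ctse (3.84 ± 0.31), and the lower gene was Ppfia4 (-3.74 ± 0.29). Ctse was read by 2 probe sets, of which 1 had the sign given. Of the type I IFN-stimulated genes 2 of 43 were higher and 0 lower, 5 and 0 over it alone in NK cells. The median was 0.40 (0.44 within the letter, camera adjusted p = 6.15e-17). In CD8a+ DC 2 of 43 were higher and 0 lower, 17 and 0 over it alone. The median was 0.65 (0.61 within the letter, camera adjusted p = 1.2e-29). In CD11b+ DC 11 of 43 were higher and 0 lower, 27 and 0 over it alone. The median was 0.95 (0.71 within the letter, camera adjusted p = 8.14e-85). Markers that passed there were those of CD8a+ DC (0 of 16 called, median -0.19, camera adjusted p = 0.0332, p = 0.701 with an estimated correlation) and T cells (0 of 11 called, median 0.31, camera adjusted p = 0.0428, p = 0.701 with an estimated correlation). In a fit of the compared cell types alone the count was 0 for NK cells and 3 for CD8a+ DC. For CD11b+ DC the count there was 11. It was 10 without uninfected WT replicate 2. In that NK fit 275 genes had an unadjusted limma p under 0.05, fewer than chance gives.

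In infected mice Mx1 (5.86 ± 0.28), Rtp4 (5.83 ± 0.54), Ifi213 (5.57 ± 0.33), Cmpk2 (5.41 ± 0.51) and Ifit1 (5.19 ± 0.54) were higher in WT than in IFNAR-KO NK cells. Cd55 (a complement regulator, -2.83 ± 0.35), Tnfsf4 (OX40 ligand, -2.51 ± 0.32), Cd83 (-1.34 ± 0.19) and Gpr25 (-1.96 ± 0.32) were lower in WT. 84 genes were higher and 9 lower. In the type I IFN list 32 of 43 were higher and 0 lower, 40 and 0 over it alone. The median was 2.72 (2.91 within the letter, camera adjusted p = 8.59e-129). Of the IFN-gamma-associated genes 4 of 20 were higher and 0 lower, 5 and 0 over it alone, with Iigp1 (4.58 ± 0.78), Gbp6 (3.26 ± 0.42) and Cxcl10 (2.09 ± 0.25). The median was 0.19 (0.20 within the letter, camera adjusted p = 3.74e-05, p = 0.118 with an estimated correlation). Ifng, near the array maximum in both, differed by -0.28 ± 1.30 (adjusted p = 0.999), which decides nothing. The markers of plasmacytoid DC (2 of 12 up, 0 down, median 0.15, camera adjusted p = 0.0195, p = 0.413 with an estimated correlation) passed too. The count was 32 in a fit of the compared cell types alone. It was 60 and 1247 (390 up, 857 down) without infected WT replicate 1 or 2.

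Infected WT CD8a+ DC had higher Ifi27l2a (6.69 ± 0.46), Ifit2 (5.80 ± 0.29), Isg20 (5.64 ± 0.46), Oas1a (5.56 ± 0.31) and Il15 (1.95 ± 0.29) than their IFNAR-KO counterparts and lower Ppfia4 (-3.66 ± 0.29), Bst1 (-2.23 ± 0.35), Tbxas1 (thromboxane synthase, -1.97 ± 0.43), Enc1 (-1.92 ± 0.30) and Serpinb1a (-1.94 ± 0.41). 205 genes were higher in WT and 59 lower. In the type I IFN-stimulated list 38 of 43 were higher and 0 lower, 43 and 0 over it alone. The median was 3.18 (3.83 within the letter, camera adjusted p = 3.87e-114). For ribosome biogenesis 0 of 26 were higher and 0 lower, 0 and 3 over it alone. The median was -0.54 (-0.65 within the letter, camera adjusted p = 7.54e-06, p = 0.374 with an estimated correlation). For the unfolded protein response 0 of 20 were higher and 0 lower, 0 and 8 over it alone. The median was -0.45 (-0.63 within the letter, camera adjusted p = 1.9e-05, p = 0.33 with an estimated correlation). Il12b differed by -0.02 ± 0.28 (adjusted p = 0.991). Past the test as well were markers of plasmacytoid DC (3 of 12 up, 0 down, median 0.19, camera adjusted p = 9.49e-04, p = 0.33 with an estimated correlation) and T cells (0 of 11 called, median 0.39, camera adjusted p = 0.0138, p = 0.808 with an estimated correlation). The count was 513 (290 up, 223 down) with the spleen pool as a block and 117 in a fit of the compared cell types alone. It was 121 and 648 (357 up, 291 down) without infected WT replicate 1 or 2 and 174 and 122 without infected IFNAR-KO replicate 1 or 2.

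In infected CD11b+ DC the antiviral genes and genes such as Lpl and Bst1 differed by genotype in opposite directions. Ifi213 (5.82 ± 0.33), Ifi27l2a (5.67 ± 0.46), Cmpk2 (5.34 ± 0.51), Ifit3 (4.88 ± 0.41), Mx1 (4.79 ± 0.28) and Il15 (3.24 ± 0.29) were higher in WT, and Lpl (-5.05 ± 0.31), Bst1 (-4.07 ± 0.35), Cd14 (a co-receptor for bacterial lipopolysaccharide, -3.73 ± 0.63), Ccr1 (-3.54 ± 0.43), Lyz2 (-3.22 ± 0.62), Fcgr3 (-3.18 ± 0.35), Hcar2 (-3.35 ± 0.53) and F10 (-3.11 ± 0.37) were lower. 240 genes were higher and 385 lower, 191 and 247 by at least 2-fold. For type I IFN-stimulated genes 37 of 43 were higher and 0 lower, 42 and 0 over it alone. The median was 2.36 (2.29 within the letter, camera adjusted p = 1.02e-63). Ribosome biogenesis genes were lower, and 0 of 26 were higher and 6 lower, 0 and 15 over it alone, with Nop16 (-1.71 ± 0.33) and Srm (-1.63 ± 0.31). The median was -0.78 (-0.80 within the letter, camera adjusted p = 1.96e-11, p = 0.146 with an estimated correlation). In the glycolysis list 0 of 18 were higher and 6 lower, 0 and 8 over it alone, with the enzymes Tpi1 (-1.72 ± 0.28) and Aldoa (-1.38 ± 0.24). The median was -0.64 (-0.63 within the letter, camera adjusted p = 3.76e-05, p = 0.146 with an estimated correlation). For oxidative phosphorylation 0 of 25 were higher and 2 lower, 0 and 9 over it alone. The median was -0.54 (-0.53 within the letter, camera adjusted p = 4.1e-06, p = 0.27 with an estimated correlation). Of the monocyte markers, which moved with these groups, 0 of 11 were higher and 3 lower, 1 and 6 over it alone. The median was -1.09 (-1.21 within the letter, camera adjusted p = 0.00521, p = 0.27 with an estimated correlation). Il12b differed by -0.57 ± 0.28 (adjusted p = 0.302). The count was 393 without the batch term, 955 with the spleen pool as a block and 341 (179 up, 162 down) in a fit of the compared cell types alone. It was 161 (107 up, 54 down) and 1034 without infected WT replicate 1 or 2 and 186 (119 up, 67 down) and 234 without infected IFNAR-KO replicate 1 or 2.

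The DC subsets of uninfected WT mice were compared as a reference for their identity. CD8a+ DC had higher Cd8a (6.92 ± 0.40), Cd36 (a scavenger receptor, 5.18 ± 0.59), Plpp1 (5.39 ± 0.49), P2ry14 (5.08 ± 0.67), Il12b (2.58 ± 0.28) and Il15 (1.73 ± 0.29), and CD11b+ DC had higher Clec4a3 (-6.14 ± 0.34), Clec4a2 (-5.04 ± 0.46), Sirpb1a (-5.32 ± 0.32), Tgm2 (a transglutaminase, -5.14 ± 0.40), Sucnr1 (-5.50 ± 0.58) and Ryr3 (-5.58 ± 0.25), with negative values for genes higher in CD11b+ DC. 497 genes were higher in CD8a+ and 548 in CD11b+ DC. Cd8a was used in the sort and is no finding. Of the CD8a+ DC markers 13 of 16 were higher and 0 lower, 14 and 0 over it alone. The median was 3.31 (3.83 within the letter, camera adjusted p = 2.91e-25). Of the CD11b+ DC markers 0 of 18 were higher and 11 lower, 0 and 14 over it alone. The median was -2.22 (-1.86 within the letter, camera adjusted p = 8.92e-17). Type I IFN-stimulated genes were lower in CD8a+ DC, and 0 of 43 were higher and 17 lower, 1 and 22 over it alone, with Rtp4 (-5.27 ± 0.54), Ifit3 (-4.83 ± 0.41) and Oasl2 (-4.47 ± 0.32). The median was -0.65 (-0.89 within the letter, camera adjusted p = 2.11e-14). Leaving out 1 array gave 630 and 487 (250 up, 237 down) without uninfected WT CD8a+ DC replicate 1 or 2 and 668 and 411 without uninfected WT CD11b+ DC replicate 1 or 2.

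NK cells of uninfected WT mice had higher Klra8 (an activating receptor for MCMV, 8.58 ± 1.44), Il18r1 (8.09 ± 0.84), Gzma (7.43 ± 1.56), Nkg7 (7.26 ± 1.16) and Ifng (6.89 ± 1.12) than the mean of the DC subsets, and lower Fscn1 (fascin, -8.90 ± 0.39), Plbd1 (-8.02 ± 0.33), Ctsh (-7.94 ± 0.16) and Tgfbi (-7.64 ± 0.35). 1693 genes were higher and 1788 lower. Of the NK cell markers 14 of 14 were higher and 0 lower, 14 and 0 over it alone. The median was 6.40 (camera adjusted p = 9.44e-16). For the NK receptors 17 of 22 were higher and 3 lower, 17 and 3 over it alone. The median was 3.06 (camera adjusted p = 2.31e-08). MHC class II genes were lower in NK cells, as 0 of 14 were higher and 14 lower, 0 and 14 over it alone, with H2-Ab1 (-6.51 ± 0.30) and H2-Eb1 (-6.47 ± 0.25). The median was -5.87 (camera adjusted p = 1.52e-25). Of the conventional DC markers 0 of 14 were higher and 12 lower, 0 and 13 over it alone. The median was -5.20 (camera adjusted p = 2.5e-16). The count was 4044 (2050 up, 1994 down) with the spleen pool as a block and 3411 (1713 up, 1698 down) with each array centred on its median. It was 2306 (1167 up, 1139 down) without uninfected WT NK replicate 2.

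The WT responses of the DC subsets differed at 30 genes, 17 with a higher change in CD8a+ DC and 13 in CD11b+ DC. Mmp12 (4.32 ± 0.65), Abca9 (3.18 ± 0.42), Col17a1 (2.88 ± 0.33), Oas1a (3.05 ± 0.45), Oasl2 (2.67 ± 0.46) and Pdcd1lg2 (2.47 ± 0.41) were higher in CD8a+ DC. Htr7 (a serotonin receptor, -3.07 ± 0.25), Ido1 (a tryptophan-degrading enzyme, -2.47 ± 0.33), Il12b (-2.44 ± 0.40), Ddx4 (-2.93 ± 0.52) and Enpp4 (-2.56 ± 0.31) were higher in CD11b+ DC. Mmp12, Abca9 and Col17a1 were among the genes that fell most in CD11b+ DC. In the type I IFN list 2 of 43 were higher and 0 lower, 10 and 0 over it alone. The median was 0.28 (camera adjusted p = 0.00706, p = 0.723 with an estimated correlation). For cytokines and chemokines 0 of 25 were higher and 1 lower, 0 and 4 over it alone. The median was -0.27 (camera adjusted p = 0.00706, p = 0.723 with an estimated correlation). The count was 36 (18 up, 18 down) without the batch term, 62 (29 up, 33 down) with the spleen pool as a block, 33 (15 up, 18 down) with a trended robust prior, 15 over genes brighter than the median probe set and 37 (16 up, 21 down) with probe sets averaged per gene. It was 22 (9 up, 13 down) and 77 without infected WT CD8a+ DC replicate 1 or 2, 11 and 14 (6 up, 8 down) without uninfected WT CD8a+ DC replicate 1 or 2, 14 (7 up, 7 down) and 11 without infected WT CD11b+ DC replicate 1 or 2 and 11 (5 up, 6 down) and 18 (9 up, 9 down) without uninfected WT CD11b+ DC replicate 1 or 2.

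Set against the mean of both DC subsets, the WT NK response was higher at 566 genes and lower at 525. Havcr2 (the inhibitory receptor TIM-3, 4.91 ± 0.61), Kctd14 (4.63 ± 0.42), Gadd45g (4.03 ± 0.82) and Ier3 (3.98 ± 0.80) were higher, and Fzd5 (-5.35 ± 0.89), Cmah (-5.01 ± 0.77), S1pr1 (-4.49 ± 0.72), Il12b (-3.72 ± 0.34), Il15 (-2.23 ± 0.37) and Cd40 (-2.35 ± 0.33) were lower. Of the ribosome biogenesis genes 12 of 26 were higher and 0 lower, 18 and 0 over it alone, with Nop16 (3.18 ± 0.42), Srm (3.07 ± 0.38) and Mybbp1a (1.93 ± 0.29). The median was 1.24 (camera adjusted p = 1.61e-15, p = 0.111 with an estimated correlation). Among type I IFN-stimulated genes 2 of 43 were higher and 11 lower, 3 and 19 over it alone, with Ifit2 (-3.28 ± 0.36) and Cmpk2 (-3.14 ± 0.64) lower and Ifi27l2a (2.54 ± 0.58) higher. The median was -0.90 (camera adjusted p = 3.44e-06, p = 0.413 with an estimated correlation). For the unfolded protein response 5 of 20 were higher and 0 lower, 6 and 0 over it alone, with Sdf2l1 (1.97 ± 0.33) and Manf (1.87 ± 0.27). The median was 0.50 (camera adjusted p = 0.00645, p = 0.449 with an estimated correlation). Of the NK effector molecules 1 of 19 were higher and 2 lower, 1 and 6 over it alone. The median was -0.85 (camera adjusted p = 0.00826, p = 0.449 with an estimated correlation). The NK cell markers moved with them, and 0 of 14 were higher and 1 lower, 0 and 1 over it alone. The median was -1.66 (camera adjusted p = 0.00333, p = 0.486 with an estimated correlation). The count was 799 (359 up, 440 down) without the batch term, 799 (359 up, 440 down) in a fit of the compared cell types alone and 956 (474 up, 482 down) with a trended robust prior. It was 2450 (990 up, 1460 down) without infected WT NK replicate 2, 341 and 560 (246 up, 314 down) without uninfected WT NK replicate 1 or 2, 848 (418 up, 430 down) and 572 (282 up, 290 down) without uninfected WT CD8a+ DC replicate 1 or 2, 639 (300 up, 339 down) without infected WT CD11b+ DC replicate 1 and 543 (252 up, 291 down) without uninfected WT CD11b+ DC replicate 1.

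Over the 15 comparisons of infection and genotype, the lists of NK activating and inhibitory receptors, conventional DC, red pulp macrophages, erythroid cells, plasma cells, platelets and neighbours of Ifnar1 passed the camera test in none. The immediate-early and dissociation stress genes passed in 2, pattern-sensing genes in 3 and the neighbours of Ptprc in 1. With an estimated correlation these passed in 0.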

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

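The tests of monocytes in place of DC were chosen after the result was seen, and those of one deviating array and of a difference before infection were not. The infection response differed between WT and IFNAR-KO cells at 23 genes in NK cells, 53 in CD8a+ DC and 42 in CD11b+ DC by the interaction test. WT responses differed between the DC subsets at 30 genes, and between NK cells and the mean of both subsets at 1091. Probe sets without a single gene symbol rose in infected WT mice too, 130 in NK cells, 112 in CD8a+ DC and 98 in CD11b+ DC, of 10143. These were 1.28%, 1.1% and 0.966% of them, against 2.9%, 1.86% and 2.21% of probe sets with a name.

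In infected CD11b+ DC, 385 genes were higher in IFNAR-KO than in WT cells, with a median of -1.16 for WT minus IFNAR-KO, and Lyz2 (-3.22 ± 0.62) and Cd14 (-3.73 ± 0.63) were among them. A difference already there before infection is argued against, since the median of these genes in uninfected mice was -0.11. Monocytes in place of DC in the IFNAR-KO sort stay open, as the conventional DC markers had a median of 0.10 for WT minus IFNAR-KO (SE over members 0.12, camera adjusted p = 0.826), below the 0.3 first set against them but by less than 2 SE, and the gate on high CD11c would remove most monocytes. A single deviating WT array stays open too, since the median of the monocyte markers was -1.09 with all arrays, -0.70 without infected WT CD11b+ DC replicate 1 and -1.18 without replicate 2, and 54 and 763 genes were lower in WT without them. A response of DC to interferon that lowers these genes may also account for them, and was not tested.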

How the results depend on the processing

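The average of the uninfected genotype contrasts and its alternatives were chosen after the data were seen, and the other settings before. The counts of called genes for centring of arrays, the trended robust prior and averaged probe sets stayed within 1.5 times the value given in the report for all comparisons. Counts below moved further, and the cause was not tested. Genes called with the spleen pool as a block numbered 2694 (WT NK cells, from 1761), 1799 (WT CD8a+ DC, from 997), 1836 (IFNAR-KO NK cells, from 1212), 368 (IFNAR-KO CD8a+ DC, from 206), 875 (IFNAR-KO CD11b+ DC, from 573), 513 (infected genotypes, CD8a+ DC, from 264), 955 (infected genotypes, CD11b+ DC, from 625) and 62 (response difference, CD8a+ DC against CD11b+ DC, from 30). Genes called in a fit of the compared cell types alone numbered 218 (WT NK cells, from 1761), 456 (WT CD8a+ DC, from 997), 132 (IFNAR-KO NK cells, from 1212), 11 (IFNAR-KO CD8a+ DC, from 206), 0 (interaction, NK cells, from 23), 11 (interaction, CD8a+ DC, from 53), 15 (interaction, CD11b+ DC, from 42), 0 (uninfected genotypes, NK cells, from 3), 3 (uninfected genotypes, CD8a+ DC, from 7), 11 (uninfected genotypes, CD11b+ DC, from 17), 32 (infected genotypes, NK cells, from 93), 117 (infected genotypes, CD8a+ DC, from 264) and 341 (infected genotypes, CD11b+ DC, from 625). Genes called without the batch term numbered 15 (interaction, NK cells, from 23) and 393 (infected genotypes, CD11b+ DC, from 625). Genes called over genes brighter than the median probe set numbered 23 (interaction, CD11b+ DC, from 42) and 15 (response difference, CD8a+ DC against CD11b+ DC, from 30). Gene lists past the test with an estimated correlation numbered 2 (WT NK cells, from 17), 3 (WT CD8a+ DC, from 15), 4 (WT CD11b+ DC, from 17), 0 (IFNAR-KO NK cells, from 17), 8 (IFNAR-KO CD8a+ DC, from 20), 8 (IFNAR-KO CD11b+ DC, from 19), 1 (interaction, NK cells, from 6), 1 (interaction, CD8a+ DC, from 5), 1 (interaction, CD11b+ DC, from 5), 1 (uninfected genotypes, NK cells, from 2), 1 (uninfected genotypes, CD8a+ DC, from 3), 1 (uninfected genotypes, CD11b+ DC, from 7), 1 (infected genotypes, NK cells, from 4), 1 (infected genotypes, CD8a+ DC, from 6) and 1 (infected genotypes, CD11b+ DC, from 7). Gene lists past the test without the batch term numbered 3 (interaction, CD8a+ DC, from 5), 4 (uninfected genotypes, CD11b+ DC, from 7) and 2 (infected genotypes, NK cells, from 4). Gene lists past the test over genes brighter than the median probe set numbered 3 (interaction, CD8a+ DC, from 5), 5 (uninfected genotypes, NK cells, from 2) and 1 (uninfected genotypes, CD8a+ DC, from 3). Gene lists past the test with the pool block numbered 5 (uninfected genotypes, CD8a+ DC, from 3). That block, which overstates infection response counts and pairs WT with IFNAR-KO cells in genotype comparisons, moved no other count by that much. The fit of single cell types has fewer degrees of freedom, and the dim filter leaves fewer genes.

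Leaving out each array in turn gave these ranges of called genes: 436 to 3856 (WT NK cells), 369 to 1572 (WT CD8a+ DC), 352 to 1715 (WT CD11b+ DC), 377 to 1360 (IFNAR-KO NK cells), 73 to 114 (IFNAR-KO CD8a+ DC), 252 to 296 (IFNAR-KO CD11b+ DC), 8 to 367 (interaction, NK cells), 27 to 189 (interaction, CD8a+ DC), 9 to 74 (interaction, CD11b+ DC), 2 to 3 (uninfected genotypes, NK cells), 5 to 6 (uninfected genotypes, CD8a+ DC), 10 to 15 (uninfected genotypes, CD11b+ DC), 60 to 1247 (infected genotypes, NK cells), 121 to 648 (infected genotypes, CD8a+ DC), 161 to 1034 (infected genotypes, CD11b+ DC), 411 to 668 (uninfected CD8a+ DC against CD11b+ DC), 2306 to 3126 (uninfected NK cells against DC), 11 to 77 (response difference, CD8a+ DC against CD11b+ DC) and 341 to 2450 (response difference, NK cells against DC). Ifnar1 averaged over groups was -0.026 with probe sets averaged, and with 1 array left out ranged from -0.28 to -0.12. The averaged uninfected genotype contrast called 31 genes, and 20 without uninfected WT NK replicate 1 and 19 without uninfected WT CD11b+ DC replicate 2. Differences that did not pass changed sign in Ifng and Il12b. Ifng (interaction, NK cells) was -0.21 and -0.052 without uninfected WT or IFNAR-KO NK replicate 1. Il12b (infected genotypes, CD8a+ DC) was 0.063 without the batch term and in a fit of the compared cell types alone. It was 0.11 and 0.19 without infected WT or IFNAR-KO CD8a+ DC replicate 2. With 1 array left out these differences ranged from -0.21 to 0.68 for Ifng (interaction, NK cells) and -0.21 to 0.19 for Il12b (infected genotypes, CD8a+ DC). Of 4054 refits of 339 gene values named in the text, 3575 kept direction and side of the threshold, 471 lost the call, 2 gained it and 6 changed sign.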

Other observations

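Tests on the Ptprc interval, interferon signalling in WT cells and tonic signalling, and the averaged contrast, were chosen after the result was seen. Those on NK RNA, Ifng and 3-prime bias were not, but the Ifng cap and bias p-values came later. Genes of oxidative phosphorylation, the mitochondrial electron transport and ATP synthesis machinery, moved up in NK cells, where in WT cells 3 of 25 rose and 0 fell, 10 and 1 over it alone, with Cycs (1.19 ± 0.19) and Cox7a2 (1.06 ± 0.22). The median was 0.48 (0.37 within the letter, camera adjusted p = 5.59e-04, p = 0.324 with an estimated correlation). In IFNAR-KO NK cells 3 of 25 rose and 0 fell, 4 and 0 over it alone, with Cycs (0.99 ± 0.19). The median was 0.38 (0.20 within the letter, camera adjusted p = 6.9e-04, p = 0.352 with an estimated correlation). In WT CD11b+ DC the list moved down, with 0 of 25 rising and 1 falling, 0 and 1 over it alone. The median was -0.22 (-0.22 within the letter, camera adjusted p = 0.0477, p = 0.597 with an estimated correlation). Of the cholesterol synthesis list in WT CD11b+ DC 0 of 17 rose and 3 fell, 0 and 5 over it alone, with Msmo1 (-1.17 ± 0.27) and Mvd (-1.13 ± 0.32). The median was -0.57 (-0.70 within the letter, camera adjusted p = 3.81e-04, p = 0.206 with an estimated correlation). In infected NK cells the median conventional DC marker stood at 1.64% of its level in infected DC, Il6 at 28.9%, Cxcl2 at 101% and Il10 at 1350%.

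Averaged over the cell types of uninfected mice, WT and IFNAR-KO cells differed at 31 genes, and 4 of the 13 outside the interferon lists, Ctse (4.44 ± 0.17), Ppfia4 (-2.54 ± 0.16), Cxcr4 (1.84 ± 0.15) and Gpr25 (-1.31 ± 0.18), were among the 257 measured neighbours of Ptprc, the gene of the CD45 alleles that mark the donors. The congenic interval of that allele stays open for these, as 0.204 were expected by chance (one-sided Fisher's exact p = 3.76e-05). The 25 neighbours fixed beforehand lack Ctse, so their 0 passes in 6 genotype comparisons (smallest camera adjusted p = 0.134) decide nothing. An interval around Ifnar1 was not tested, as the 4 were picked near Ptprc, on another chromosome. Type I interferon signalling stays open, since the median absolute interaction of the called neighbours, 0.355, is below the 0.5 first set against it, but Irf9, an interferon-list gene called in the same contrast, had only 0.157. Chance is argued against for the count of 31, not each gene, as 1 of 100 splits, the real one, gave as many (highest other 8, also in the 30 others parting every pair).

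NK cell markers stood at 1.26 to 11.5% of their NK level in infected DC arrays and 0.8 to 2.42% in uninfected ones, higher in pool 1 than in pool 2 in each infected group, although DC were gated as NKp46-negative. NK cells or their RNA in the sorted DC may be the source and stay open, since the 14 markers correlated over the DC arrays with a median pairwise r of 0.669, short of the bound set. Whether Ifng comes only from such RNA stays open, as the median ratio of its share to the marker share, 4.13, decides nothing where Ifng was the brightest gene of all 4 infected NK arrays and its level there may be capped. A 3-prime bias of single arrays stays open, with Spearman's rho 0.762, over the 0.7 set for it but with an adjusted p that did not pass (exact permutation p = 0.0368, adjusted 0.147 over 4 tests) and Pearson's r 0.449 (exact p = 0.272, adjusted 0.363) over the infected arrays, and r 0.59 without the arrays farthest from the median. Over the uninfected arrays rho was 0.667 (exact p = 0.0831, adjusted 0.166) and r 0.283 (exact p = 0.483, adjusted 0.483), and expression of these genes by infected DC themselves was not tested.

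Type I IFN-stimulated genes were higher in CD11b+ than in CD8a+ DC of uninfected mice by a median of 0.65 in WT cells, with 17 of 43 called, and by 0.34 in IFNAR-KO cells, with 10 higher and 1 lower (unadjusted camera p = 2.26e-05, unadjusted p = 0.0615 with an estimated correlation). Tonic signalling through IFNAR may account for part of the gap, as the difference of the gaps had a median of 0.27 (unadjusted camera p = 2.15e-06, unadjusted p = 0.0403 with an estimated correlation). As the whole cause, such signalling on these cells is argued against only for the 10 genes called higher in CD11b+ DC of IFNAR-KO cells. For the list it stays open, as Fisher's exact test (one-sided p = 7.7e-06, 1.78 expected by chance) takes genes as independent. The IFNAR-KO list means were 7.24 and 7.72 in CD11b+ DC and 6.97 in CD8a+ DC arrays. Other causes of that gap were not tested.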
